A study of Pseudomonas putida KT2440 with 6 samples.

How the data were processed

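Gene expression of Pseudomonas putida KT2440, a soil bacterium used as a laboratory and production strain, was measured on 6 Affymetrix arrays, 3 with RNA from cells at 30 °C and 3 with RNA from the cold. Per the labels' protocols, cells grew in a 1.5 L fermenter in minimal medium with 15 mM succinate as the only carbon source, and were sampled at an optical density of about 0.8 just before the medium was cooled and again 2 h after it had reached 10 °C. RNA was labelled with biotin and hybridised to an array of the KT2440 genome with 1 sample per array. The labels call the samples of a group biological replicates, while the growth protocol describes samples taken side by side for RNA extraction, so the p-values measure only the spread between these samples, which may be technical. The 10 °C samples were also taken later than the 30 °C samples, so time in the fermenter and temperature changed together.

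The authors deposited one intensity per probe set and array, on a linear scale, for 8047 probe sets. How probe values were summarised, corrected for background and normalised is not given in the sources used here. The median intensity of the genes was 74.9, 72.6 and 65.7 on the 30 °C arrays and 64.8, 69.8 and 64.9 on the 10 °C arrays. A second deposited table holds the authors' own comparison: per the file headers it gives geometric mean intensities of both classes, their fold change (10 °C over 30 °C, a ratio) and the p-value and false discovery rate of a test with a random variance model. Its means equal the geometric means of the deposited intensities times 1.01 at 10 °C and 0.900 at 30 °C, so its log2 changes lie 0.16 above those from the intensities. For 203 probe sets it gives the p-value and the false discovery rate only as an upper limit of 1e-07, and both were read as that limit. No 2 arrays had more than 4 probe sets with identical values.

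Of the probe sets, 5330 carry a locus tag and stand for 5323 genes, of which 1356 also have a gene symbol. Another 2443 cover intergenic regions, 229 carry no locus tag, and 45 are controls of the array maker. Genes are named by the symbol in the deposited table, or by locus tag where it gives none. None of the locus tags (0) is listed in the gene table of assembly LBNL_KT2440_1968 used here, so names came from the deposited table alone and no gene coordinates are given. Control probe sets were left out of all tests. For 7 genes with a pair of probe sets the log2 values were averaged.

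Intensities were used as log2(intensity + 1), with no further normalisation. Fold changes are on this scale, which understates the change of dim genes. Each gene was fitted with limma (version 3.58.1, lmFit and eBayes, in R 4.3.3) with temperature as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the 5323 genes, with an adjusted p of 0.05 as the threshold. Every adjusted p of a gene comes from this fit and every log2 change is 10 °C minus 30 °C, given ± its SE with 3 arrays per temperature. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. A direct exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so the number of arrays limits the precision and the tests borrow the spread from all genes.

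Gene lists were fixed before the data were examined, by symbol and product name, and 34 lists with at least 3 measured members were tested with camera, with a preset correlation between genes of 0.01 and adjustment over the lists. Every adjusted p of a list comes from camera unless another test is named. Some patterns caught genes outside a list's name, such as rimK among the ribosomal proteins, greA and greB among the translation factors and phenylacetate genes called pha among those of polyhydroxyalkanoate. In the list of RNA helicases and RNA degradation, csdA is annotated as a cysteine sulfinate desulfinase. The rule for named genes was also fixed beforehand. It took the 10 genes with the largest rises and the 10 with the largest falls among those past the threshold whose arrays did not overlap, for each list past the threshold the members past it with the largest change in either direction, up to 4 per list, all members of the cold shock protein list, the largest member of a reported run of neighbours, and a set of genes of cold adaptation, heat shock, RNA turnover and succinate use. Of that set, deaD, rhlE, rnr, hfq, desA and cbrB are not listed under these symbols in the table used here. Genes named outside the rule are said to have been chosen after their values were seen.

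Probe sets without a locus tag have names of genes of catabolic and conjugative plasmids, such as xyl, nah and tra, and KT2440 was cured of its plasmid. The 218 of them not marked as shared with other sequences were taken as a measure of background. Their 95th percentile, between 23.6 and 48.2 on the 6 arrays, was used as the background level of an array, a choice made after seeing the data. A gene at or below it on all 3 arrays of a group was read as not above background there. For such a gene, and for one at or below it on 2 of the 3 arrays, only a bound is given, as "at least N-fold", from the mean of the bright group against the mean over the dim group's arrays of the higher of the background level and the gene's own value. Both groups' measured means are kept with it. By this measure 963 genes were not above background at either temperature.

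The procedure was tested on simulated data with the real genes' means and spreads for the same comparison of 3 arrays against 3. Of the 5323 genes 200 were changed. Of those changed 1.5-fold, 41.8% were recovered, and of those changed 2-fold and 4-fold, 100% each, with 6 calls among the unchanged genes. In a simulation of the gene lists with camera, a list with a shift of −1 on the log2 scale was called (adjusted p = 2.39e-76) and 0 of the others were. Simulated genes were drawn independently, with the same spread at both temperatures and with no offset between the arrays. In the data 3053 genes passed, far more than the 200 changed in the simulation, and the adjustment is then less strict. The shares recovered and the 6 calls therefore do not carry over to the data. In the real lists the estimated correlation between genes reached 0.74, so the simulation does not test lists whose genes move together. The alternatives were quantile normalisation, median centring, the authors' deposited table, a pseudocount of 16, a filter on the dimmest 25% of genes, the replicate number as a block, a variance trend with robust fitting, another rule for genes with several probe sets, each array left out in turn, limma's treat against a fold of 1.5, and for lists an estimated correlation, fry and ranks. For the lists, the deposited table was tested with cameraPR on signed scores from its p-values, and the variance trend was run without robust fitting, which camera does not offer. With an estimated correlation camera also takes its degrees of freedom from the arrays, 4 here, which by itself makes a call harder to reach. 3 further ones were added after seeing the data: a filter on the background level, quantile normalisation without the third 30 °C array, and the median of the 218 background probe sets subtracted from each array on the log2 scale. The last shifts all genes of an array by the same amount, bright and dim alike. It is thus a change of scale and does not remove background. It lowers the third 30 °C array most, where the median intensity of these probe sets was 17.0. Intergenic regions were tested with the same model, apart from the genes.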

Results

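The arrays compared the transcript levels of P. putida cells growing on succinate at 30 °C with those of cells 2 h after the medium had been cooled to 10 °C, with 3 arrays per temperature. The question was how the expression of the genome changes after a sudden drop in temperature. Across genes, arrays of the same temperature correlated with r between 0.976 and 0.993 at 30 °C and with r of 0.996 at 10 °C, against 0.846 to 0.871 between temperatures, where genes are not independent replicates. The third 30 °C array stood apart from the other two at 30 °C, and the median SD of a gene on the log2 scale was 0.22 at 30 °C against 0.10 at 10 °C. Without that array it was 0.12 at 30 °C.

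After 2 h at 10 °C the transcripts of the main heat shock chaperones had dropped to a small part of their level at 30 °C. Among the largest falls were those of htpG, the chaperone of the Hsp90 family (log2 change −5.26 ± 0.20), of grpE, the nucleotide exchange factor of DnaK (−5.26 ± 0.15), and of the chaperonin genes groEL (−5.04 ± 0.12) and groES (−4.72 ± 0.18). The intensity of groEL went from 8250 at 30 °C to 250.3 at 10 °C. At the other end, PP1690 and PP1691, neighbours annotated only as hypothetical proteins, were among the genes with the largest rises. PP1690 was not above background at 30 °C and at least 126-fold higher at 10 °C (adjusted p = 3.25e-10), and PP1691 went from 57 to 7836 (7.08 ± 0.19).

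In all, 3053 of the 5323 genes passed the threshold, 1124 of them higher and 1929 lower at 10 °C. A change of at least 2-fold was seen for 1271 of them, 552 higher and 719 lower, a split whose direction depended on the scaling. The arrays of the temperatures did not overlap for 3559 genes, 66.9%, where chance gives 10% if no offset divides the arrays. All 218 background probe sets had a lower mean at 10 °C, so an offset could separate genes too. The median of all genes lay at −0.22 and went to −0.05 after quantile normalisation, a shift of the whole distribution against which small changes have to be read. After quantile normalisation 1465 genes were higher and 1492 lower, and of those changed at least 2-fold 657 were higher and 583 lower. By the authors' own values 1317 were higher and 1332 lower, and 694 and 576 at 2-fold. With the median background of each array subtracted on the log2 scale, which shifts bright and dim genes alike, the split turned to 1441 higher and 677 lower. At 2-fold it was 886 and 410. Under that setting the falls of cspA-1, gyrA, infA, parC, pnp and PP5405 lost their calls. The setting is a change of scale that does not remove background, and this holds wherever it is named below. For each gene named here as risen or fallen, all 3 arrays of one temperature lay above all 3 of the other. The rule required this of the 10 largest rises and the 10 largest falls.

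**Figure D1:**
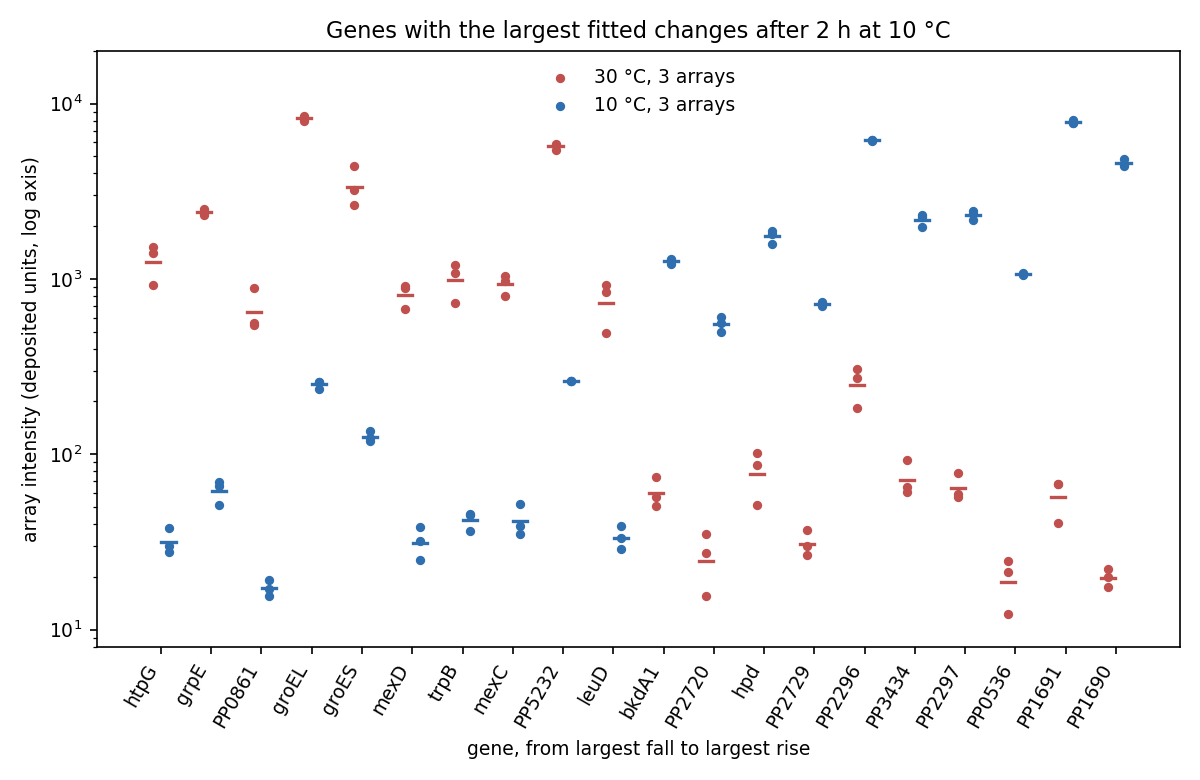
Intensity on each of the 6 arrays (log axis, deposited units) of the 10 genes with the largest falls and the 10 with the largest rises by fitted change; points are arrays, red for 30 °C and blue for 10 °C, and bars are geometric means. Only genes whose 3 arrays of one temperature lie apart from the 3 of the other were eligible, such as groEL with means of 8250 and 250.3.

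Besides the chaperones, the largest falls included mexC (−4.46 ± 0.17) and mexD (−4.66 ± 0.18) of a multidrug efflux pump, trpB of tryptophan synthesis (−4.51 ± 0.20), leuD of leucine synthesis (−4.40 ± 0.23) and the hypothetical protein gene PP5232 (−4.44 ± 0.12). The ferric siderophore receptor gene PP0861 had an intensity of 644.5 at 30 °C and was not above background at 10 °C, a fall of at least 24.6-fold (adjusted p = 4.07e-08). The largest rises included PP2297, annotated as the integrase of the integrative element Ppu40 (5.15 ± 0.15), and its neighbour PP2296 (4.64 ± 0.18). Also among them were hpd, the 4-hydroxyphenylpyruvate dioxygenase of tyrosine breakdown (4.49 ± 0.22), with its neighbour PP3434 (4.90 ± 0.17), and bkdA1 of branched-chain keto acid oxidation (4.38 ± 0.16). PP2720, at background on 2 of the 3 arrays at 30 °C, was at least 14.7-fold higher. PP0536 was at least 29.2-fold and PP2729 at least 19.8-fold higher at 10 °C, both from levels not above background at 30 °C (adjusted p = 4.07e-08 and 1.92e-08).

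Of the 26 genes of chaperones and heat shock proteases, 19 fell and 4 rose, and adjusted over the list alone 20 fell and 4 rose (adjusted p = 5.2e-04). With an estimated correlation the call was lost (adjusted p = 0.684). Falls were seen for dnaK, the Hsp70 chaperone (−3.85 ± 0.16), and for tig, the ribosome-bound trigger factor (−1.87 ± 0.19). The 4 that rose were rpoH, which encodes the heat shock sigma factor (1.00 ± 0.22), PP3312, PP3313 (1.11 ± 0.14) and the small heat shock protein gene PP3314. PP3314 was at background on 2 of the 3 arrays at 30 °C and at least 2.59-fold higher at 10 °C. PP3312, chosen after its values were seen, was not above background at 30 °C and at least 1.56-fold higher at 10 °C.

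The list of cold shock proteins, small nucleic-acid binding proteins with a cold shock domain, did not pass as a list (adjusted p = 0.492, and 0.856 with an estimated correlation). Of its 7 members 3 rose and 2 fell, and the same counts held when adjusted over the list alone. PP1099 rose from 2732 to 8524 (1.64 ± 0.15), PP0636 by 1.58 ± 0.32 and cspD by 1.38 ± 0.15. PP0985 fell from 3848 to 840.3 (−2.19 ± 0.15) and cspA-1 from 366.8 to 239.6 (−0.61 ± 0.15), a call lost with the median background subtracted (adjusted p = 0.5, from 1.15e-04 to 0.5 over the alternatives). The values of PP1209 (−0.17 ± 0.13) and cspA-2 (0.00 ± 0.16, at an intensity of 2627 in the cold) did not pass, and the sign of the latter's value is open.

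**Figure D2:**
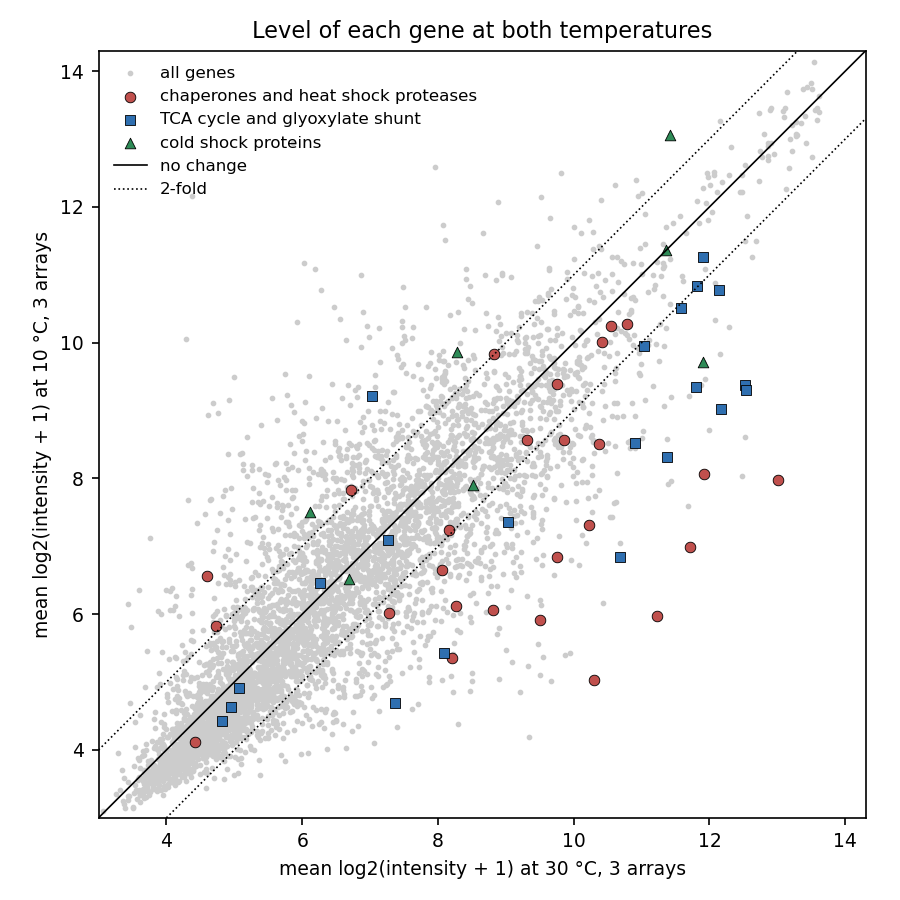
Mean log2(intensity + 1) of each of the 5323 genes at 30 °C (x axis) and 10 °C (y axis), 3 arrays each, with members of 3 lists marked; the solid line is no change and the dotted lines are 2-fold. Most chaperone and TCA cycle genes lie below the lines, with groEL falling from 8250 to 250.3, while cold shock protein genes lie on both sides.

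Genes of translation moved in both directions. rbfA, a ribosome maturation factor known from the cold response of other bacteria, rose by 2.07 ± 0.18, infB, which encodes translation initiation factor 2, by 1.21 ± 0.12 and nusA, a transcription elongation factor, by 1.48 ± 0.20. These 3 genes lie next to each other by locus tag. The value of infA passed (−0.63 ± 0.21, adjusted p = 0.0242) but no longer did when any single 10 °C array was left out, by the authors' own values, or with the median background subtracted, with adjusted p from 0.00442 to 0.565 over the alternatives. The value of infC did not pass (0.04 ± 0.12), at an intensity of 7854 at 10 °C. Larger falls were those of the elongation factor genes efp (−2.25 ± 0.13) and tsf (−2.04 ± 0.19), chosen after their values were seen. By at least 2-fold, 1 gene listed as a translation factor rose and 5 fell. Of the 17 genes listed as translation factors 3 rose and 8 fell (adjusted p = 0.644), of the 7 of ribosome assembly 3 rose and 1 fell (adjusted p = 0.16), and of the 56 listed as ribosomal proteins 8 rose and 12 fell (adjusted p = 0.586). Adjusted over the list alone, these were 3 and 8, 3 and 1, and 5 and 7. The ribosomal counts depended on the third 30 °C array and on the scaling, with 8 and 18 without that array, 12 and 10 after quantile normalisation, 16 and 5 by the authors' own values, and 15 and 1 with the median background subtracted. The translation factor counts were 3 and 10 without that array, 5 and 7 after quantile normalisation, 4 and 5 by the authors' own values, and 5 and 4 with the median background subtracted. For ribosome assembly they were 4 and 2 without that array, and 4 and 1 after quantile normalisation or by the authors' own values. With the median background subtracted they were 4 and 0. The median of the ribosomal list was −0.09, while camera, which compares it with all genes, placed it upwards.

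Of 23 genes of aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 16 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.0135, but adjusted p = 0.856 with an estimated correlation). With the median background subtracted only 7 fell and 2 rose. Falls were largest for gltX (−1.96 ± 0.18) and also seen for valS (−1.47 ± 0.16), while thrS rose by 1.43 ± 0.15.

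Of 15 genes listed as RNA helicases and RNA degradation 6 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.162). Without the third 30 °C array 6 rose and 5 fell, and with the median background subtracted 7 rose and 1 fell. The helicase gene rhlB rose by 0.56 ± 0.14, and pnp, which encodes polynucleotide phosphorylase, fell (−0.99 ± 0.16), a call lost with the median background subtracted (adjusted p = 0.086). The value of rne, the ribonuclease E gene, did not pass (−0.35 ± 0.15, adjusted p = 0.0711). The DEAD-box helicase gene PP1868, chosen after its values were seen, rose from 805.5 to 3638 (2.17 ± 0.16).

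Genes of the TCA cycle and of NADH dehydrogenase and ATP synthase mostly fell. Of the 21 genes of the TCA cycle and glyoxylate shunt 16 fell and 1 rose, also when adjusted over the list alone (adjusted p = 1.15e-04, but adjusted p = 0.684 with an estimated correlation), with a median of −1.36, and with the median background subtracted 12 fell and 1 rose. Falls were seen for aceA, the isocitrate lyase of the glyoxylate shunt (−3.83 ± 0.12), and sucC, a subunit of succinyl-CoA synthetase (−3.23 ± 0.15). The exception was mqo-2, 1 of 3 genes annotated as malate:quinone oxidoreductase, which rose by 2.18 ± 0.14. Of the 23 genes of NADH dehydrogenase and ATP synthase 20 fell and 0 rose, also when adjusted over the list alone (adjusted p = 1.41e-06, but adjusted p = 0.684 with an estimated correlation), and with the median background subtracted 16 fell and 0 rose. Falls were seen for nouK, annotated as subunit K of NADH dehydrogenase (−2.46 ± 0.15), and atpC (−2.57 ± 0.16). The uptake gene for succinate, dctA, fell from 2289 to 655.3 (−1.80 ± 0.12). Of the 6 genes of C4-dicarboxylate uptake 4 fell and 1 rose, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.223). With the median background subtracted 2 fell and 1 rose.

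Genes of biosynthesis also fell more often than they rose. Of 76 genes of amino acid biosynthesis 52 fell and 1 rose, and 54 fell and 3 rose when adjusted over the list alone (adjusted p = 2.1e-07, but adjusted p = 0.684 with an estimated correlation), and with the median background subtracted 36 fell and 3 rose. trpB and leuD had the largest falls of the list, and aroE-1, a shikimate dehydrogenase gene, rose by 0.54 ± 0.17. Of 35 genes of nucleotide biosynthesis 26 fell and 1 rose, also when adjusted over the list alone (adjusted p = 1.15e-04, but adjusted p = 0.684 with an estimated correlation), and with the median background subtracted 16 fell and 2 rose. Falls were seen for upp (−2.49 ± 0.13) and pyrF (−2.43 ± 0.15), and pyrD rose by 0.39 ± 0.13. Of 21 genes of fatty acid biosynthesis 13 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.0316, but adjusted p = 0.684 with an estimated correlation), but with the median background subtracted only 5 fell and 3 rose. accC-1 (−2.56 ± 0.14) and accB (−2.49 ± 0.15) of acetyl-CoA carboxylase fell, and fabD rose by 0.52 ± 0.16. This list no longer passed without the first 30 °C array, or with quantile normalisation without the third, and 16 of the 18 alternatives that kept the preset correlation kept the call (adjusted p from 0.0236 to 0.0504). The small rises of aroE-1, pyrD and fabD did not pass with some single arrays left out, and that of pyrD also with the replicate block, with adjusted p of up to 0.0664, 0.0986 and 0.0732 over the alternatives.

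Falls outnumbered rises among genes of nutrient uptake, too. Of 40 genes of iron and siderophore uptake 26 fell and 5 rose, also when adjusted over the list alone (adjusted p = 0.0186, but adjusted p = 0.684 with an estimated correlation). After quantile normalisation 19 fell and 6 rose, and with the median background subtracted 14 fell and 5 rose. A fall was seen for pfrI, annotated as a ferric regulator (−3.90 ± 0.26). Among those that rose were fepA, the enterobactin receptor gene (2.24 ± 0.19), and bfr, which encodes the iron store bacterioferritin and so is no uptake gene (1.91 ± 0.14). Of 48 genes of phosphate and sulfur starvation 26 fell and 3 rose, also when adjusted over the list alone (adjusted p = 0.00913, but adjusted p = 0.684 with an estimated correlation), and with the median background subtracted 17 fell and 5 rose. The falls were led by the sulfate genes cysP (−3.52 ± 0.16) and cysNC (−2.95 ± 0.17). The rises were led by phoQ (2.52 ± 0.16) and phoP (1.71 ± 0.17), a sensor and regulator known for magnesium and envelope stress and not for phosphate starvation. Of 80 genes of amino acid transport 46 fell and 8 rose, and 47 fell and 8 rose when adjusted over the list alone (adjusted p = 0.00788, but adjusted p = 0.684 with an estimated correlation), and with the median background subtracted 25 fell and 12 rose. Falls were seen for PP1070 (−2.63 ± 0.14) and PP0657 (−2.38 ± 0.16), while the basic amino acid permease genes PP4485 (1.51 ± 0.21) and PP4484 (1.23 ± 0.16) rose.

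**Figure D3:**
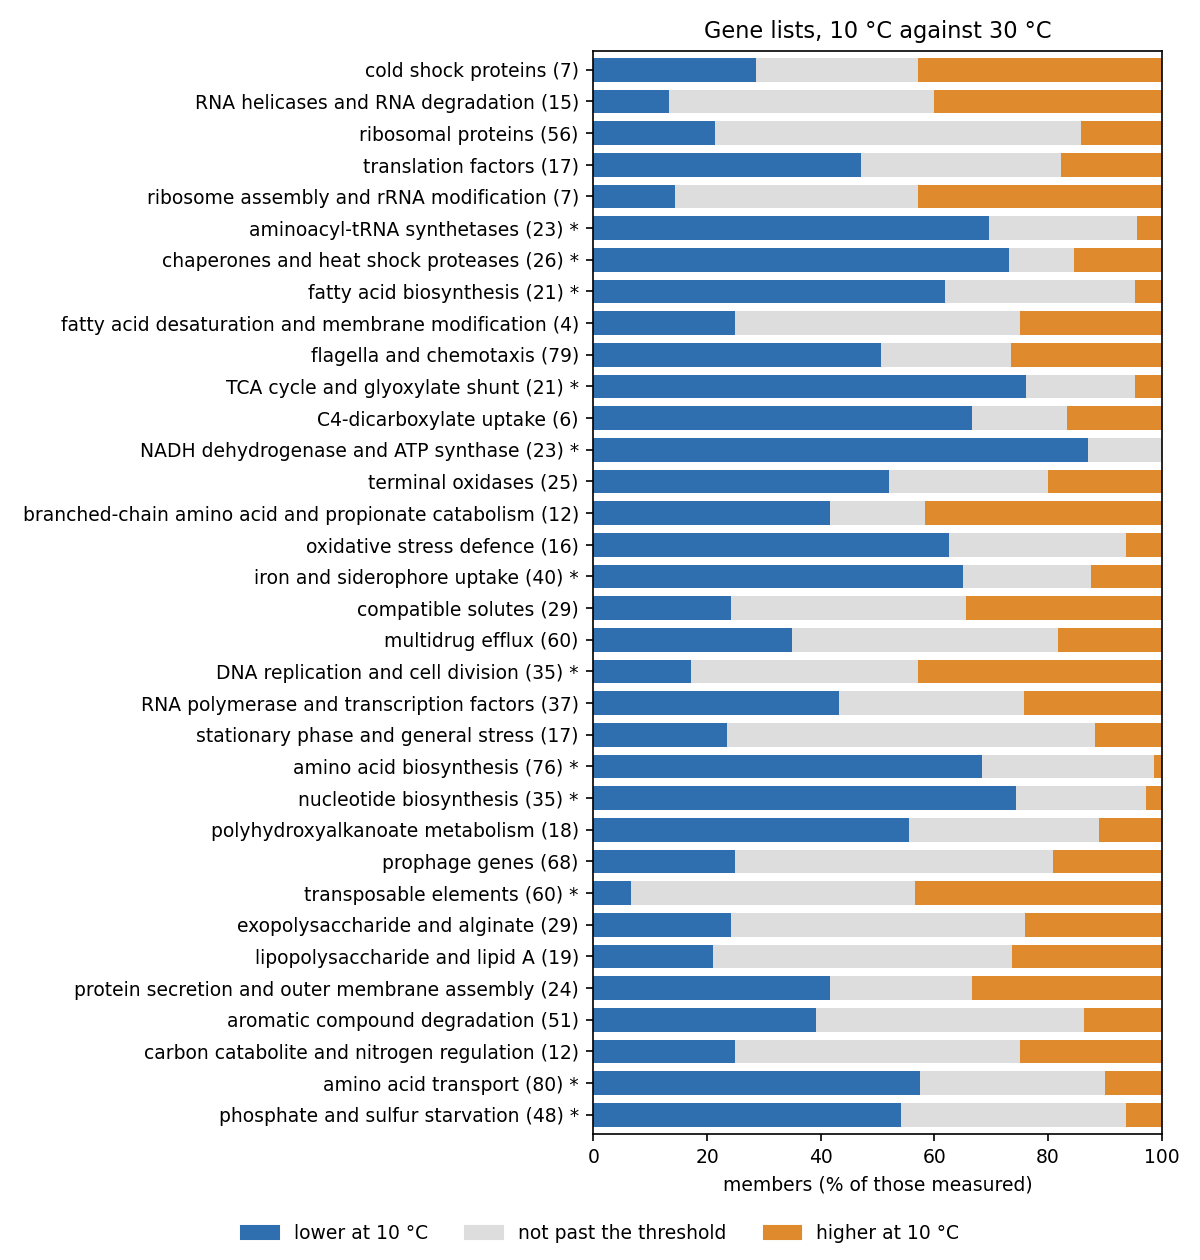
Share of the measured members of each of the 34 gene lists (number measured in brackets) that were lower, higher or not past the threshold at 10 °C against 30 °C; a star marks the 12 lists past the threshold with the preset correlation. The share lower is largest for NADH dehydrogenase and ATP synthase, with 20 of 23 genes, and the share higher exceeds the share lower in both starred lists that rose.

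There were 2 lists that shifted upwards. Of 60 genes of transposable elements 26 rose and 4 fell, and 25 rose and 3 fell when adjusted over the list alone (adjusted p = 9.48e-06, but adjusted p = 0.684 with an estimated correlation). Without the third 30 °C array 28 rose and 8 fell, and with the median background subtracted 35 rose and 0 fell. For 44 of the 60 the probe set is marked as shared between sequences, so copies of one element are not separate observations. PP1133, a transposase of the repeated element ISPpu9 with such a probe set, rose by 1.94 ± 0.15, and PP5407, a transposition protein gene, was at least 2.81-fold higher from a level not above background at 30 °C. PP5405 fell (−1.14 ± 0.27), a call lost with the median background subtracted (adjusted p = 0.159). PP0014 was at or near background at both temperatures, so no fold is given, and its call was lost after quantile normalisation (adjusted p = 0.0735, from 0.00327 to 0.485 over the alternatives). Of 35 genes of DNA replication and cell division 15 rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.0186, but adjusted p = 0.856 with an estimated correlation). dnaB, the replicative helicase, rose by 1.82 ± 0.16 and rodA by 1.43 ± 0.28, while parC (−0.87 ± 0.15) and gyrA (−0.68 ± 0.12), subunits of topoisomerases, fell, both calls lost with the median background subtracted (adjusted p of 0.144 and 0.264). With that setting 15 rose and 0 fell. Without the third 30 °C array 14 rose and 13 fell, and the list no longer passed (adjusted p = 0.149, from 0.00419 to 0.149 over the 18 alternatives that kept the preset correlation, of which 14 kept the call).

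Among other genes fixed beforehand, rpoS, which encodes the sigma factor of the general stress response, rose by 0.56 ± 0.18 and recA by 0.42 ± 0.13. Both calls were lost with some single 10 °C arrays left out, with adjusted p of up to 0.0842 for rpoS and 0.084 for recA. The values of cti, the fatty acid cis-trans isomerase gene (−0.29 ± 0.16, adjusted p = 0.137), and of crc, a gene of carbon catabolite control (−0.21 ± 0.13, adjusted p = 0.177), did not pass. Without the third 30 °C array cti passed (−0.39, adjusted p = 0.0223, up to 0.748 over the alternatives), and so did rne (−0.41, adjusted p = 0.0249, up to 0.907).

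With the correlation between genes estimated for each list, 0 of the 34 lists passed the threshold in camera, the smallest adjusted p being 0.684, and 0 had an unadjusted p under 0.05, against 13 with the preset correlation. The rotation test fry, which asks whether a list's genes move one way and does not compare them with other genes, called 24 lists, among them 11 of the 12, but not DNA replication and cell division (adjusted p = 0.2).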

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

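The tests of the signal level and of shared probe sets and the splits of the arrays were chosen before their results were seen. Intergenic regions lay outside the comparison of genes. Of the 2443 intergenic regions 614 passed the threshold, 427 higher and 187 lower at 10 °C, and 207 were at least 2-fold higher against 42 at least 2-fold lower. Among the largest rises by fitted change in regions with a probe set not marked as shared was that from 2624763 to 2624994, from an intensity of 171 to 4064 (log2 change 4.56 ± 0.11, SE, 3 arrays per temperature). The regions from 184561 to 184653 and from 564347 to 564518 were not above background at 30 °C and at least 9.90-fold and 6.88-fold higher at 10 °C. The region from 5919299 to 5919405, at background on 2 of the 3 arrays at 30 °C, was at least 7.44-fold higher, and that from 4370185 to 4370304, at background on 1 of them, rose by 3.09 ± 0.41. Positions are those of the deposited table, on the KT2440 chromosome of a build not given in the sources used here, and the genes beside them were not placed.

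Intergenic regions thus rose more often than they fell (69.5% of those past the threshold), and more often than genes, of which 36.8% did. In 1000 draws of genes matched to the regions' mean levels the share of rises had a median of 29.9% and at most 33.5%, which argues against their lower signal level. With shared probe sets left out on both sides the share was 66.4% of regions, 172 higher and 87 lower, against 36.2% of genes, which argues against the 1338 shared probe sets as the cause. Transcription from outside the annotated genes, or past their ends, in the cold may account for it, but which genes flank each region was not analysed here, so this stays open.

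After quantile normalisation 534 regions were higher and 146 lower, and without the third 30 °C array 517 and 246. With 3 arrays per temperature there are only 10 splits of the arrays, too few for a share under 0.05. The real split, 1 of the 10, gave 614 regions in limma and the highest other split gave 0. At an unadjusted p under 0.05 the real split gave 927 regions and the highest other split gave 102. The other splits mix both temperatures in each group, so the change with temperature enters their spread and few calls there are built in.

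Among the 229 probe sets without a locus tag, 7 were higher at 10 °C and 0 lower in limma, with 114 at an unadjusted p under 0.05. All 7 have probe sets marked as shared with other sequences, and they include those annotated as putative cointegrate resolution proteins (1.61 ± 0.15 for protein S and 0.71 ± 0.14 for protein T).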

How the results depend on the processing

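The filter on the background level, quantile normalisation without the third 30 °C array and the subtraction of the median background were chosen after seeing the data, and all other settings before. The count of 3053 genes became 1230 with limma's treat against a fold of 1.5, a stricter question by construction, and stayed between 2415 and 3475 with single arrays left out. The other settings gave counts within 1.5 times of 3053. The count of 1271 genes changed at least 2-fold lay between 1257 and 1300 with single arrays left out, and at 1003 with a pseudocount of 16. Subtracting the median background gave 2118 genes, of which 1801 were shared, 1296 changed at least 2-fold and 13 lists. The count of 12 lists became 0 with an estimated correlation, a setting that also leaves camera 4 degrees of freedom. It became 24 with fry, which asks another question and shared 11 of the 12. With single arrays left out 11 to 13 passed. DNA replication and cell division also lost its call without the dimmest genes (adjusted p = 0.0745), with genes above background (0.0587), with quantile normalisation without the third 30 °C array (0.0528) and with fry (0.2), and the cause was not tested. Oxidative stress defence (adjusted p = 0.0537) passed under 9 of 18 settings, with adjusted p from 0.0322 to 0.111, and exopolysaccharide and alginate (0.162) under 2, from 0.0176 to 0.18. Same-numbered arrays did not deviate together (correlations of −0.289, 0.001 and −0.079 across genes). This cannot show whether they came from the same culture, since the third 30 °C array dominated the spread at 30 °C. With the replicate block 3010 genes, 1271 genes changed at least 2-fold and 13 lists passed. For the 79 named genes, 1312 of 1342 values under other settings stayed on their side of the threshold, 27 lost and 3 gained a call, and 0 reversed. Quantile normalisation shared 2592 calls with the main setting, and the authors' deposited table shared 2456. Signal over background limits the dim genes: 963 were not above it at either temperature, and for those above it at one temperature a fold is only a bound.

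There are only 10 splits of 6 arrays into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 3053 genes, 1271 genes changed at least 2-fold and 12 lists, and the highest of the others gave 0, 0 and 9. At an unadjusted p under 0.05 in limma the real split gave 3348 genes and the highest of the others 63. Each other split mixes both temperatures, in unequal numbers, in each group. The change with temperature thus enters their spread and part of their contrast. They are no comparison without an effect, and neither their 0 genes nor their 9 lists measure false calls.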

Other observations

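The genes in this part that the rule for named genes does not cover, and the tests of runs of neighbours, of the direction of change and of the third 30 °C array, were chosen after the results were seen. Of 29 genes of compatible solutes 10 rose and 7 fell (adjusted p = 0.169, with a median of −0.12 but camera pointing upwards against all genes). The counts were 11 and 10 without the third 30 °C array, 10 and 4 after quantile normalisation, 11 and 4 by the authors' own values, and 11 and 2 with the median background subtracted. The 4 neighbours PP0868 to PP0871, annotated as an ABC transporter of glycine betaine, carnitine and choline, rose by 3.28 ± 0.15, 3.07 ± 0.13, 3.79 ± 0.25 and 3.33 ± 0.23. Other genes of the list annotated for betaine transport or binding moved either way: PP0076 rose (1.15 ± 0.13), PP3957 fell (−1.62 ± 0.18), and PP0294, PP0295 and PP0296 did not pass. Of 12 genes of branched-chain amino acid and propionate catabolism 5 rose and 5 fell (adjusted p = 0.176). The rises were those of bkdA1, bkdA2 (3.45 ± 0.15), bkdB (3.23 ± 0.13) and lpdV (3.10 ± 0.16), the subunits of the branched-chain keto acid dehydrogenase, and of mmsA-1. The regulator of envelope stress algT rose from 472 to 4324 (3.19 ± 0.18), together with its neighbours mucA (2.69 ± 0.16) and algN (2.95 ± 0.20). Of 12 genes from PP1277 to PP1288, which hold the alginate synthesis genes, 0 rose and 5 fell in limma, after quantile normalisation 0 rose and 2 fell, and with the median background subtracted 0 rose and 0 fell. Of these, algD was not above background at either temperature. Outside this stretch, pprA (4.13 ± 0.15) and algZ (1.20 ± 0.13), both annotated for alginate biosynthesis, rose. Of the 29 genes of exopolysaccharide and alginate, which include algT, 7 rose and 7 fell (adjusted p = 0.162). After quantile normalisation the counts were 10 and 3, and with the median background subtracted 10 and 0.

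Of 79 flagella and chemotaxis genes 21 rose and 40 fell (adjusted p = 0.644). The counts were 25 and 34 after quantile normalisation, 21 and 29 by the authors' own values, and 25 and 18 with the median background subtracted. Falls were seen for flgG (−2.14 ± 0.15), fliE (−2.05 ± 0.13) and fleQ (−1.51 ± 0.15), while the rod genes flgB (−0.30, adjusted p = 0.179) and flgC (−0.31, adjusted p = 0.113) did not pass, and the cap protein gene fliD (1.69 ± 0.17), flgM (1.03 ± 0.13) and the receptor gene PP4658 (2.74 ± 0.19) rose. Of 25 genes of terminal oxidases 5 rose and 13 fell (adjusted p = 0.482), 8 and 10 after quantile normalisation, 7 and 10 by the authors' own values, and 7 and 5 with the median background subtracted, with a fall of ccoO-2 of a cbb3-type oxidase (−2.34 ± 0.16). The 5 that rose were all annotated as ubiquinol oxidase genes, such as cyoA (0.41 ± 0.14). Of 16 genes of oxidative stress defence 10 fell and 1 rose (adjusted p = 0.0537), 5 and 2 with the median background subtracted, with a fall of sodB (−2.46 ± 0.14) and a rise of katA (0.98 ± 0.14). Of 15 genes annotated as sigma-70 factors of the ECF subfamily or as putative ones, 12 fell and 0 rose, such as PP0704 (−3.36 ± 0.16), and after quantile normalisation 12 fell and 1 rose, and with the median background subtracted 9 and 1. PP4611, 1 of them and at background on 2 of the 3 arrays at 10 °C, was at least 7.75-fold lower. The group, formed by annotation after the values were seen, leaves out algT, annotated as a sigma-H factor, which rose (3.19 ± 0.18). Among 4 genes of fatty acid desaturation and membrane modification, cfa of cyclopropane fatty acid synthesis was at least 3.17-fold higher from a level not above background at 30 °C, and the desaturase family gene PP0217 fell (−0.52 ± 0.13), a call lost by the authors' own values (false discovery rate 0.0547) and with the median background subtracted (adjusted p = 0.645), with the list not past the threshold (adjusted p = 0.67). Of 18 genes listed under polyhydroxyalkanoate metabolism, many of them phenylacetate genes, 2 rose and 10 fell (adjusted p = 0.335), after quantile normalisation 2 rose and 4 fell, and with the median background subtracted 2 rose and 2 fell. Adjusted over the list alone, the terminal oxidase counts were 6 and 13, and those of the other lists in this part were the same.

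Genes changed at least 2-fold lay in runs of neighbouring locus tags. Of these 1271 genes 341 lay in 68 runs of 4 or more that moved the same way, 23 higher and 45 lower, against at most 37 genes in 10000 shuffles of the order. Runs made up mostly of genes with no symbol included PP3312 to PP3318, in which PP3317, at background on 2 of the 3 arrays at 30 °C, was at least 13.3-fold higher. They also included PP0738 to PP0744, which holds phrB and hemH and in which PP0742 rose by 3.55 ± 0.28, and PP1159 to PP1164, with PP1160 (3.28 ± 0.12).

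More genes fell than rose with the deposited intensities, 63.2% of those past the threshold. All 218 background probe sets had a lower mean at 10 °C, with a median change of −0.36, so a higher background on the 30 °C arrays may have lowered dim genes in the comparison. Without the third 30 °C array, which had the highest background, the share lower was 64.7%, so leaving that array out did not reduce it. Among genes above background the share was 59.2%, and in the brightest 25% of genes it was 55.7%, a value too close to the bound set for this test, which was widened by the counting spread after the value was seen, to decide. A scaling offset between the arrays of both temperatures cannot be told apart from a true excess of falls: after quantile normalisation 50.5% were lower, but this method makes the distributions alike, and 0 control probe sets lay above background on every array to serve as a reference. With the median of the background probe sets subtracted on each array, 1441 genes were higher and 677 lower, 32% lower, so the direction turned, though this moves bright and dim genes alike.

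The third 30 °C array differed from the other 30 °C arrays. If its cells had been cooled in part, it would hold part of the change to 10 °C. This was taken over 487 genes higher and 810 lower at 10 °C by at least 2-fold against the other 30 °C arrays. Set against unchanged genes of the same level, the median share of that change was 0.00847, which argues against partial cooling. Its background probe sets lay 0.415 above those of the other 30 °C arrays, and its deviation fell with the level of a gene (rho = −0.608 across genes, which are not independent replicates), with medians of 0.26 in the dimmest and −0.35 in the brightest 25%. A higher background and a narrower range of signal on that array may account for it, and its source was not tested.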
